A study of Mus musculus with 96 samples.

How the data were processed

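Liver RNA from 96 Ldlr-/- mice fed a Western diet (WD) or a reference diet (RD; LFD in the diet field) on a B6;129S7 background was measured with a 3' tag kit, per the labels: 48 females and 48 males, 80 on WD (8 per sex at each of 5 durations) and 16 on RD (4 per sex at 1 week and 10 months). The labels give a separate mouse for each library and no batch, litter or cage. No paired analysis was possible because every library came from another animal. Reads were aligned to NCBIM37 with TopHat2 2.1.1 and counted with HTSeq 0.6.0, per the submitters' processing notes. The deposited values are log2 RPM (reads per M reads), quantile normalised by the authors, for 11409 genes. Their rule for keeping genes is not given in the sources, and a table repeating the labels was not used.

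Tied values in each library step by whole reads, so depth was rebuilt from the spacing of the first 40 levels, starting at level 5. It ran from 0.300 to 4.24 M reads (14.2-fold; median 1.07), with 3.27% to 34.5% of genes at 0, and reads rebuilt from the table summed to 82.5% to 99.2% of that depth. The median depths were 0.451 M reads in male RD livers at 10 months, 0.452 at 1 week, and 1.20 in male WD livers at 1 week; in females they were 1.11 on RD and 0.659 on WD at 1 week and 0.451 and 0.532 at 10 months. Libraries of the same group correlated at 0.812 to 0.975 (median 0.930 over 304 pairs), no 2 libraries were identical, and the chi-square over degrees of freedom of the rebuilt reads was 2.55 or more (median 10.7). The highest value is the same in 69 libraries and a lower one in the rest, so the quantile step limits how far the top genes can differ. The file had lost or damaged 1229 gene symbols, of which 1196 were named again from the GENCODE M1 annotation of NCBIM37, and 33 kept only an ID; coordinates come from the same annotation, matched for 11375 IDs.

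Samples formed 14 groups of sex, diet and duration. limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) was fitted to the deposited log2 values with 1 mean per group over all 96 libraries; a gene was tested if above 0 in at least 4 libraries, which kept 11409, and passed at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were WD against RD within sex at 1 week and 10 months, the differences of these effects between sexes and durations, WD at each later duration against 1 week, an F test over 5 durations, RD at 10 months against 1 week, and sex within RD. Fixed gene lists, 33 besides the sex chromosome check (Xist, Ddx3y), were tested with limma camera (preset correlation 0.01, and an estimated one), for 32 with at least 3 measured members; of adipocyte and pancreas markers only Cela1 and Cfd were measured. A list level is the mean over members of the deviation from each gene's mean over 96 libraries; WD and RD animals were compared by a 2-sided exact permutation test over 495 splits (smallest p 0.00202), adjusted over 128 tests. The scripts recovered simulated changes of 1.5-fold for 9.52% to 14.3% of genes. With no difference median calls were 0 to 22, but up to 189.5 in other splits of the real libraries.

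Named genes were set by rule: in diet comparisons the 5 largest rises and falls among passing genes without overlap between groups, 4 of each in the differences, RD and sex comparisons and 5 of each for WD 10 months against 1 week, up to 3 members of each list by adjusted p with 1 of opposite sign, and 15 genes in every diet comparison; predicted genes were skipped. The groups, comparisons, tests, gene lists, naming rule and a first set of alternatives were fixed before the data were examined; alternatives based on depth, rebuilt reads, mitochondrial RNA and residuals were added later. Alternatives changed the filter, the pseudocount, centring (which moved libraries by −0.333 to 0.127), weights, the trend, the groups in the fit, depth (reads drawn to 0.300 M) and covariates, and left out each library in turn. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.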

Results

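The series followed liver gene expression in Ldlr-/- mice fed a Western diet (WD) used to induce steatohepatitis, or a reference diet (RD). It held 96 livers: 8 WD animals per sex at 1 week and 1, 2, 5 and 10 months. RD had 4 animals per sex at 1 week and 10 months. Values were log2 RPM from a 3' tag kit. Rebuilt sequencing depth ran from 0.30 to 4.24 M reads (median 1.07), with 3.27% to 34.5% of genes at 0 in a library. A single read stood at 0.78 to 2.24 in female and 1.98 to 2.61 in male RD libraries at 1 week and at 1.57 to 2.75 and 1.78 to 2.57 at 10 months. Lower WD values cannot be told from the 0 of these libraries. Depth and RNA composition went with the groups: among females the 2 mitochondrial ribosomal RNAs averaged 14.96 ± 0.21 (SD) on RD and 11.98 ± 0.40 on WD at 1 week, and among males 13.55 ± 0.89 and 15.07 ± 0.11. At 10 months the same means were 13.47 ± 0.87 on RD and 14.45 ± 0.73 on WD in females, and 13.72 ± 0.29 and 14.91 ± 0.16 in males. The quantile step capped these means at 15.12, where most male WD libraries at 1 week stood. Effects below are log2 differences ± SE from limma with n = 8 WD against 4 RD animals unless said otherwise. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and only genes that passed are said to have risen or fallen. List counts give members higher or lower of those measured, with calls adjusted over all genes, and beside them in square brackets the counts adjusted over the list alone. List levels are mean deviations per animal (WD minus RD). With 8 against 4 animals, 0.404% of genes are expected to show no overlap between the groups by chance.

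**Figure D1:**
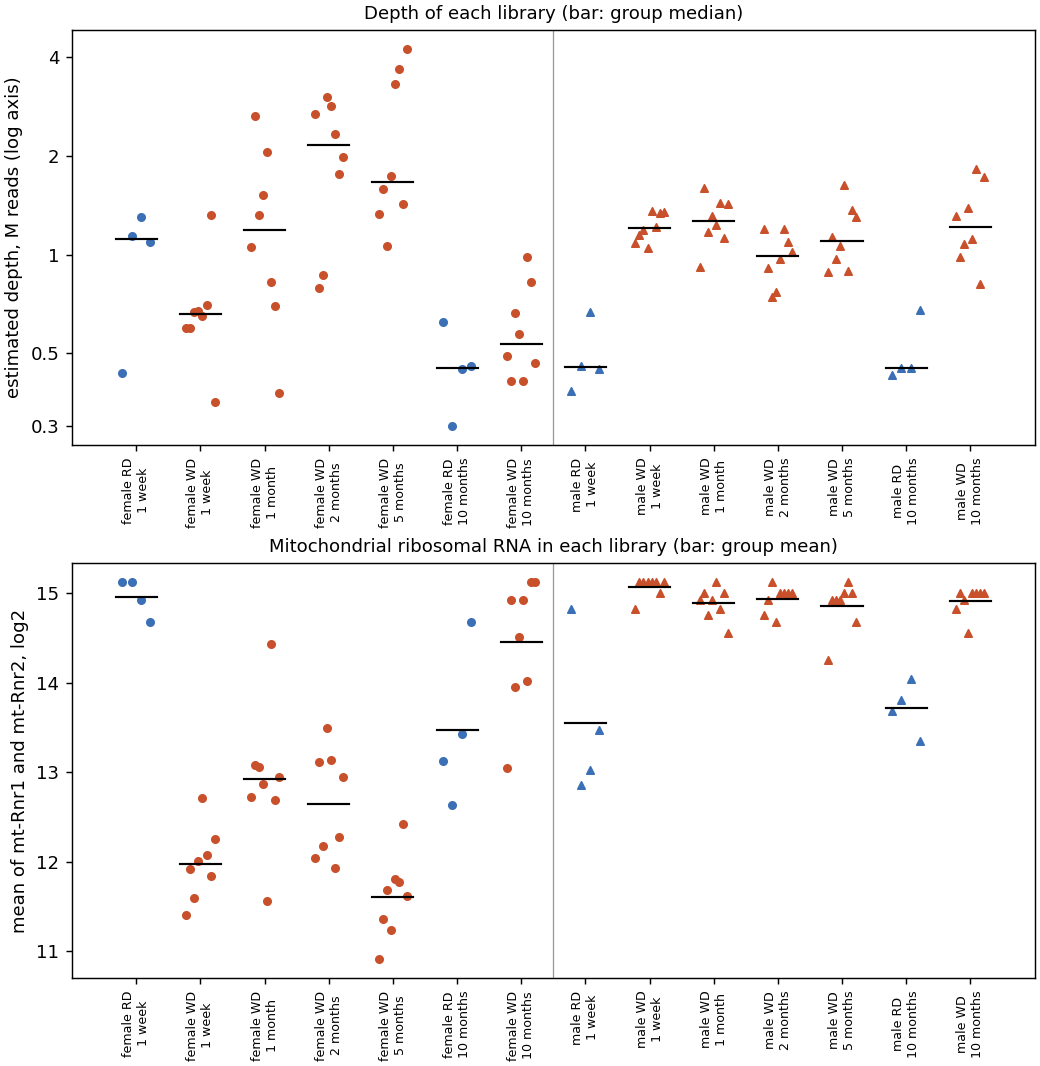
Estimated depth (M reads, log axis, bar at the group median) and mean of the 2 mitochondrial ribosomal RNAs (log2, bar at the group mean) of each of 96 libraries by sex, diet and duration. Female group means of the RNAs ran from 11.60 on WD at 5 months to 14.96 on RD at 1 week.

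Ldlr, the receptor that takes up low density lipoprotein and the gene disrupted in these mice (ENSMUSG00000032193, chromosome 9, 21528038 to 21554360 of NCBIM37), still gave 3' reads in every group. In females its values ran from 4.51 to 5.22 (RD 1 week), 4.0 to 5.24 (RD 10 months), 4.43 to 6.79 (WD 1 week), 0 to 5.31 (1 month), 3.87 to 4.59 (2 months), 4.13 to 4.9 (5 months) and 3.63 to 5.04 (10 months). In males the ranges were 5.33 to 6.35 and 5.33 to 6.24 on RD, then 5.17 to 6.37, 4.68 to 5.63, 4.72 to 5.46, 3.75 to 5.04 and 4.18 to 5.20 on WD. The tag kit reads only the 3' end and the removed part of the gene is not given in the sources, so these values do not check the genotype.

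Sex labels and RD livers of the sexes were compared first (n = 8 males against 8 females, both durations pooled). Xist, the RNA of the inactive X chromosome, was −6.25 ± 0.41 in males relative to females, and Ddx3y, a Y-linked helicase, was 7.17 ± 0.37; over all 96 libraries Xist spanned 7.12 to 8.81 in females and 0 to 3.71 in males, and Ddx3y 0 to 3.72 and 7.32 to 8.36. Cyp4a12a, a male-specific fatty acid hydroxylase (ENSMUSG00000066071, chromosome 4, 114971651 to 115005420), stood 7.32 ± 0.45 log2 units higher in males (limma adjusted p = 1.7e-26), beside its paralog Cyp4a12b (6.28 ± 0.34) and the urinary protein gene Mup11 (6.0 ± 0.69). Sult2a1, which sulfates bile acids and steroids (ENSMUSG00000078798, chromosome 7, 14381601 to 14422759), was −7.26 ± 0.54, followed by Cyp2a4, a testosterone hydroxylase, at −6.19 ± 0.51 and Sult3a1 at −5.48 ± 0.43. The male-biased list had 15 of 19 higher [15] (camera adjusted p = 6.7e-05 with an estimated correlation). The female-biased list had 18 of 18 lower [18] (adjusted p = 1.7e-05 with an estimated correlation). In all 3798 genes differed (1568 higher and 2230 lower in males); with reads drawn to equal depth the split had 767 higher and 1718 lower, and with reads at their own depth 1172 higher and 2731 lower. The Mup, Cyp4a12 and Cyp2a genes are close paralogs, so single members are uncertain with 3' tags.

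Does 1 week of WD already change the female liver? Limma camera passed 13 of 32 lists (11 higher, 2 lower), all lost with adjusted p = 0.134 to 0.318 with an estimated correlation. Saa3, an inflammation-induced serum amyloid (ENSMUSG00000040026, chromosome 7, 53967368 to 53971046), rose by 4.38 ± 0.63 (limma adjusted p = 6.6e-08), with the plasma proteins Orm3 at 2.80 ± 0.45 and Hpx, which binds haem, at 1.26 ± 0.23. Lgals3, a galectin of lipid-laden macrophages (ENSMUSG00000050335, chromosome 14, 47987426 to 48005835), rose by 1.88 ± 0.33 (limma adjusted p = 7.3e-06), Capg by 2.02 ± 0.41 and Gpnmb, a lysosomal glycoprotein of such cells, by 3.11 ± 0.78. Ppara, the nuclear receptor that switches on fat burning in fasting (ENSMUSG00000022383, chromosome 15, 85565413 to 85633249), fell (−2.04 ± 0.23, limma adjusted p = 2.4e-11), together with its targets Acadm (−1.5 ± 0.25) and Ehhadh (−2.92 ± 0.54). The monocyte genes Cybb (1.42 ± 0.24) and Lyz2 (1.5 ± 0.32) also rose.

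Per animal, the acute phase list was higher by 1.63, exact permutation adjusted p = 0.0123, with 10 of 16 higher [11]. Lipid-associated macrophage genes had 7 of 16 higher [10], a level difference of 1.11, exact permutation adjusted p = 0.0185; chemokine genes had 8 of 17 higher [9], with 0.99, exact permutation adjusted p = 0.0250. Among hepatocyte zones 5 of 12 higher [5] passed for periportal genes (level 0.63, exact permutation adjusted p = 0.0123), led by Cyp2f2 at 1.37 ± 0.21, Sult5a1 at 2.46 ± 0.56 and Aldh1b1 at 0.99 ± 0.28, and 4 of 12 higher [4] for pericentral genes (level 0.57, exact permutation adjusted p = 0.0185), led by Cyp1a2 at 1.30 ± 0.26. Fatty acid oxidation had 7 of 22 lower [7] with a level of −0.69, exact permutation adjusted p = 0.0123. The mitochondrial genome list had a level of −0.53, exact permutation adjusted p = 0.0123, with 3 of 9 lower [3]. Cell cycle genes had a level of 0.6, exact permutation adjusted p = 0.0123, but only 2 higher and 1 lower of 17 [3 and 1], with Cdk1, the mitotic kinase, at 0 in every RD library and at 0 to 3.72 on WD, Cdkn1a, a brake on division, at −1.78 ± 0.46 and Birc5 at 1.46 ± 0.39.

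Monocyte and macrophage markers had 10 of 16 higher [12]. Resident Kupffer cell markers had 2 of 9 higher [6]. The male-biased list had 5 of 19 higher [6], led by the paralog-prone Serpina1e (4.09 ± 0.68) and Mup11 (3.61 ± 0.84). Genes of the oxidative stress factor NRF2 went 1 higher and 3 lower of 13 [1 and 3], with Gclm at −1.44 ± 0.17, Txnrd1 at −1.28 ± 0.26 and Hmox1 at 1.01 ± 0.28. In the cholesterol synthesis list 2 higher and 6 lower of 23 [2 and 7] passed, with Stard4 at −1.70 ± 0.33 and Hsd17b7 at −1.36 ± 0.30; the hepatocyte identity list had 4 higher and 1 lower of 14 [6 and 1], with the liver factor Cebpa at 0.83 ± 0.19. Circadian clock genes had 2 higher and 3 lower of 13 [2 and 3] (Clock −1.22 ± 0.24, Tef 0.73 ± 0.20). Lipid droplet genes had 3 of 17 lower [3] (Pparg −2.14 ± 0.59, Plin2 −0.98 ± 0.28). Interferon genes had 1 higher and 1 lower of 17 [2 and 1] (Irf7 0.96 ± 0.25, Ifit2 −2.03 ± 0.58). Bile acid genes had 2 higher and 1 lower of 15 [2 and 1] (Abcc2 −2.02 ± 0.24, Hsd3b7 0.83 ± 0.21). Female-biased genes had 2 higher and 1 lower of 18 [2 and 1]. Collagen and matrix genes had 2 higher and 1 lower of 30 [2 and 1]. LXR targets had 3 of 9 higher [3]. Stellate genes had 1 of 15 higher [0]. Endothelial genes had 1 of 14 higher [1]. Cholangiocyte genes had 1 of 10 higher [1] (Sox9 1.23 ± 0.33). Unfolded protein response genes had 1 of 12 lower [1] (Pdia4 −1.21 ± 0.31). With limma no member passed among fatty acid synthesis (20 measured, 0 at unadjusted p under 0.05), neutrophil markers (7, 2), T and NK cell markers (10, 3), B and plasma cell markers (9, 0), oncofetal genes (8, 1), erythrocyte markers (6, 0) and ribosomal proteins (7, 0).

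The largest rises with no overlap between groups were Saa3, Cyp2c54 (4.12 ± 0.64), Serpina1e, the drug-metabolising Cyp2b10 (3.10 ± 0.55) and Saa1 (3.07 ± 0.66), and the largest falls the bilirubin-conjugating family member Ugt1a5 (−4.44 ± 0.61), the kinase Tec (−3.98 ± 0.51), Gprin3 (−3.81 ± 0.51), the glycogen regulator Ppp1r3g (−3.77 ± 0.80) and Sephs2 (−3.72 ± 0.42). Among genes followed in every comparison, Clec4f, a Kupffer cell lectin, rose by 1.14 ± 0.25 and Cidec, a lipid droplet protein, stood at −1.11 ± 0.55 without passing. Cyp7a1, the rate-limiting bile acid enzyme, stood at 1.53 ± 0.39 and lost its call without RD replicate 3 (1.2, adjusted p = 0.0507); Col1a1 (1.86 ± 0.64) lost it without RD replicate 1 or 3 (1.25 at the lowest, adjusted p up to 0.251), and Trem2 (1.73 ± 0.58) without any 1 of RD replicate 1 or 3 or WD replicate 1, 3, 6 or 7 (1.48 at the lowest, adjusted p up to 0.123). Spp1 (1.65 ± 0.66) passed only without RD replicate 2 (2.14, adjusted p = 0.0331). The rest did not pass: Ldlr −0.06 ± 0.39, Srebf1 −0.03 ± 0.74, Pcsk9 −0.39 ± 0.66, Timp1 −0.16 ± 0.59, Timd4 0.85 ± 0.46, Cd36 −0.58 ± 0.28, Afp 0.08 ± 0.48 and Ly6d −0.06 ± 0.61. Of the adipocyte and pancreas markers, Cela1 stood at 0.92 ± 0.34, a call lost without RD replicate 1, 2 or 3 or WD replicate 2 or 3 (adjusted p up to 0.250), and Cfd at −1.23 ± 0.91. In all 1896 genes passed (112 to 3742 under other settings; 661 higher, 1235 lower; 934 higher and 1064 lower after centring every library), 1024 of them without overlap. Camera calls were also lost with the mitochondrial genome mean as a covariate for LXR targets (adjusted p = 0.243), fatty acid oxidation (0.134), Kupffer markers (0.143), cell cycle (0.232) and mitochondrial genome (0.878). Calls were lost with the ribosomal RNA covariate for pericentral genes (0.0868) and mitochondrial genome (0.373), at equal depth for LXR targets (0.160) and cell cycle (0.270) and from rebuilt reads for cell cycle (0.0851). Camera and the median or mean of the members took opposite signs for fatty acid synthesis, female-biased, unfolded protein response, circadian clock and ribosomal proteins. Of 78 genes named by rule that passed, 55 also passed with reads drawn to equal depth, 65 with only the compared groups fitted, 76 with array weights and 10 with the mitochondrial ribosomal RNAs as a covariate, in this text Saa3, Lgals3, Cybb, Cdk1, Hsd17b7, Cebpa, Plin2 and Ugt1a5. With this covariate the estimates of Ifit2 (0.58), Pdia4 (0.31) and Txnrd1 (0.36) turned positive; at equal depth Gpnmb, Birc5, Hmox1, Sox9, Col1a1, Trem2 and Cela1 lost their calls. The per-animal level tests passed for 13 of 32 lists, and for 8 without RD replicate 1.

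In males at 1 week no list passed limma camera, so changes are given as single genes and as list levels per animal. Ppara rose by 2.15 ± 0.23 (limma adjusted p = 1.8e-12), with the mitochondrial dehydrogenases Acadm (ENSMUSG00000062908, chromosome 3, 153585321 to 153607596) at 1.44 ± 0.25 and Acadvl at 2.62 ± 0.48, while the carnitine enzyme Cpt2 fell, at −0.79 ± 0.17. Ccnd1, the cyclin that starts the cell cycle (ENSMUSG00000070348, chromosome 7, 152115836 to 152125774), rose by 2.72 ± 0.42 and Top2a, a replication enzyme, by 2.78 ± 0.62; Cenpe, a centromere motor, was listed at 0 in every RD library and at 1.18 to 2.97 on WD. Pdia4, an endoplasmic reticulum chaperone (ENSMUSG00000025823, chromosome 6, 47746141 to 47763511), rose by 3.03 ± 0.31 (limma adjusted p = 7.0e-13). Among male-biased genes Ugt2b1 reached 2.12 ± 0.26 and the steroid enzyme Hsd3b5 3.56 ± 0.64, Ugt2b38 stood at 0 in every RD library and at 1.45 to 3.49 on WD, and among female-biased genes Cyp17a1 fell (−2.35 ± 0.43), A1bg (−2.29 ± 0.57) and Cyp2a4 (−2.51 ± 0.63).

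Per animal the male-biased list stood at 1.05 (5 of 19 higher [5]) and the female-biased at −0.70 (6 of 18 lower [6]). The cell cycle list stood at 0.83 (5 of 17 higher [5]). The unfolded protein response stood at 0.67 (5 higher and 1 lower of 12 [5 and 1]). All of these had exact permutation adjusted p = 0.0123. Ddit3 of the last list was at 0 in every RD library and 1.72 to 3.88 on WD, and Trib3 at −1.22 ± 0.28. LXR targets, genes of a sterol-sensing receptor, had a level of 0.59, exact permutation adjusted p = 0.0185 and counts of 3 higher and 1 lower of 9 [3 and 1], led by Soat1 at 1.80 ± 0.33. The interferon list (5 of 17 higher [5]; level 0.59, exact permutation adjusted p = 0.0185) lost its level call without RD replicate 4 (adjusted p = 0.0506); its members Gbp2 (1.57 to 3.63 on WD) and Zbp1 (0.90 to 2.96) were at 0 in every RD library and Ifit2 rose by 2.20 ± 0.58. Collagen and matrix genes had 6 higher and 2 lower of 30 [6 and 2]. Fatty acid oxidation genes had 4 higher and 8 lower of 22 [4 and 8]. Cholesterol synthesis genes had 3 higher and 2 lower of 23 [3 and 2], with Dhcr24 at 3.26 ± 0.36 and Mvk at 2.30 ± 0.51. Lipid-associated macrophage genes split 2 higher and 2 lower of 16 [2 and 2]: Fabp5, a fatty acid carrier, rose by 4.22 ± 0.53, the protease Ctsb fell (−0.90 ± 0.22), and Lgals3 rose by 1.33 ± 0.33. NRF2 genes had 4 higher and 2 lower of 13 [5 and 2] (Gclm 1.18 ± 0.17, Srxn1 −1.02 ± 0.22, Txnrd1 0.87 ± 0.26). Bile acid genes had 4 higher and 1 lower of 15 [6 and 3] (Abcc2 1.74 ± 0.24, Slco1b2 1.06 ± 0.19). Hepatocyte identity genes had 4 of 14 higher [4] (Apoa1 1.67 ± 0.25, Cps1 1.12 ± 0.30).

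Lipid droplet genes had 2 higher and 4 lower of 17 [2 and 4] (Pnpla2, a fat-releasing lipase, −1.08 ± 0.19, Plin3 −0.75 ± 0.20). Fatty acid synthesis had 1 higher and 4 lower of 20 [1 and 1] (Fads1 −1.11 ± 0.21). The clock had 1 higher and 2 lower of 13 [1 and 2] (Dbp 2.47 ± 0.53). Acute phase genes had 2 higher and 3 lower of 16 [2 and 3] (Apcs −1.54 ± 0.44). Chemokines had 1 higher and 2 lower of 17 [1 and 1] (Cxcl9 1.53 ± 0.38). Stellate genes had 3 of 15 higher [2] (Vim 1.01 ± 0.30). Monocyte genes had 1 of 16 higher [1] (Mpeg1, a phagocyte pore protein, 1.59 ± 0.37). Kupffer cell markers had 1 higher and 1 lower of 9 [1 and 0] (Cd5l 1.05 ± 0.30). Erythrocyte genes had 2 higher and 1 lower of 6 [3 and 1] (Alas2 at 0 in every RD library, 0 to 2.57 on WD). The mitochondrial genome had 1 higher and 2 lower of 9 [1 and 2]. Ribosomal proteins had 2 of 7 lower [3] (Rpl32 −0.78 ± 0.21). Pericentral genes had 1 higher and 2 lower of 12 [1 and 2]. Periportal genes had 2 of 12 lower [2]. T and NK cell markers had 1 of 10 higher [1]. Endothelial markers had 1 of 14 higher [1]. Cholangiocyte markers had 1 of 10 lower [1]. Oncofetal genes had 1 of 8 lower [0]. With limma no member passed among neutrophil markers (7 measured, 0 at unadjusted p under 0.05) and B and plasma cell markers (9, 0).

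The largest male rises without overlap were Fabp5, the adipokine Rarres2 (4.07 ± 0.56), Ino80e (3.72 ± 0.53), and Ilf2 and Pawr, both at 0 in every RD library and at 3.46 to 4.68 and 2.64 to 4.80 on WD; the largest falls were Alg14 (−2.64 ± 0.59), Cyp2a4, Rasl11b (−2.44 ± 0.51), Hsf1, the heat shock factor (−2.43 ± 0.51), and Cyp17a1. Col1a1 (2.12 ± 0.64) lost its call without RD replicate 1 or 2 (adjusted p up to 0.0626) and Ly6d (−1.70 ± 0.61) without RD replicate 2, WD replicate 4 or WD replicate 8 (adjusted p up to 0.139). Cyp7a1 (0.90 ± 0.39) passed only without RD replicate 2 or WD replicate 7 (adjusted p down to 0.0304), and Cidec (−1.24 ± 0.55) only without WD replicate 5 (adjusted p = 0.0423). The others followed throughout did not pass: Ldlr 0.15 ± 0.39, Srebf1 −0.68 ± 0.74, Pcsk9 −0.57 ± 0.66, Timp1 −1.02 ± 0.59, Trem2 0.59 ± 0.58, Gpnmb −0.68 ± 0.78, Spp1 0.70 ± 0.66, Clec4f 0.21 ± 0.25, Timd4 0.03 ± 0.46 and Cd36 0.22 ± 0.28. Afp was at 0 in every RD library and at 0 to 0.98 on WD, all under the value of 1 read in the RD libraries, and did not pass. Of the pancreas and adipocyte markers Cela1 stood at −0.87 ± 0.34, a call lost without RD replicate 1, 3 or 4 or WD replicate 5, 6 or 8 (adjusted p up to 0.0843), and Cfd at 1.54 ± 0.91. In all 3539 genes passed (1705 to 4167 under other settings; 2365 higher, 1174 lower; 1787 higher and 1891 lower after centring, and 2916 higher and 847 lower from rebuilt reads), 1346 without overlap; limma camera passed 0 of 32 lists (4 at unadjusted p under 0.05; 3 without RD replicate 2, 4 without WD replicate 6, 1 without WD replicate 2 or 3). Signs differed between camera and the members for cholesterol synthesis, Kupffer cell, neutrophil, B and plasma cell, pericentral, periportal, chemokines, acute phase response, NRF2 and oncofetal. Of 94 genes named by rule that passed, 61 also passed with reads drawn to equal depth, 70 with only the compared groups fitted, 63 with array weights and 50 with the mitochondrial ribosomal RNAs as a covariate. With this covariate Trib3, Ifit2, Txnrd1, Cps1, Plin3, Apcs, Vim, Mpeg1, Ly6d and Cela1 lost their calls; at equal depth Cenpe, A1bg, Cyp2a4, Gbp2, Zbp1, Txnrd1, Alas2, Rasl11b, Hsf1, Col1a1 and Ly6d lost their calls. Level tests (not at equal depth) passed for 9 lists, and for 5 without RD replicate 4. RD libraries had 24.6% to 33.2% of genes at 0 and WD 10.0% to 13.6%, so depth may raise levels of low genes.

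The diet effect at 1 week was then compared between the sexes (male effect minus female effect). Ugt1a5 (ENSMUSG00000089943, chromosome 1, 90062587 to 90115572), one of a family sharing its 3' end, had the largest positive difference at 7.54 ± 0.86 (limma adjusted p = 7.1e-12), followed by the RNA-binding Ilf2 (6.58 ± 0.63), Tec (6.43 ± 0.72) and the kinase Cdc42bpb (6.43 ± 0.79). Negative differences were led by Cyp2c54 (−4.61 ± 0.90), Cyp2b10 (ENSMUSG00000030483, chromosome 7, 26682639 to 26711643; −4.35 ± 0.78), Orm3 (−4.23 ± 0.63) and Nxt1 (−4.20 ± 0.87). Acute phase genes had 9 of 16 lower [10], and camera gave adjusted p = 0.00128, and adjusted p = 0.946 with an estimated correlation. Across all genes the female and male effects ran against each other (Pearson r = −0.44): 990 genes passed in both sexes with opposite signs where 324 were expected from independent calls, while 44 were higher and 8 lower in both (137 and 127 expected). In all 4004 differences passed (320 to 4842 under other settings; 2523 positive, 1481 negative; 2002 positive and 2306 negative after centring), and 320 with the mitochondrial ribosomal RNAs as a covariate.

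**Figure D2:**
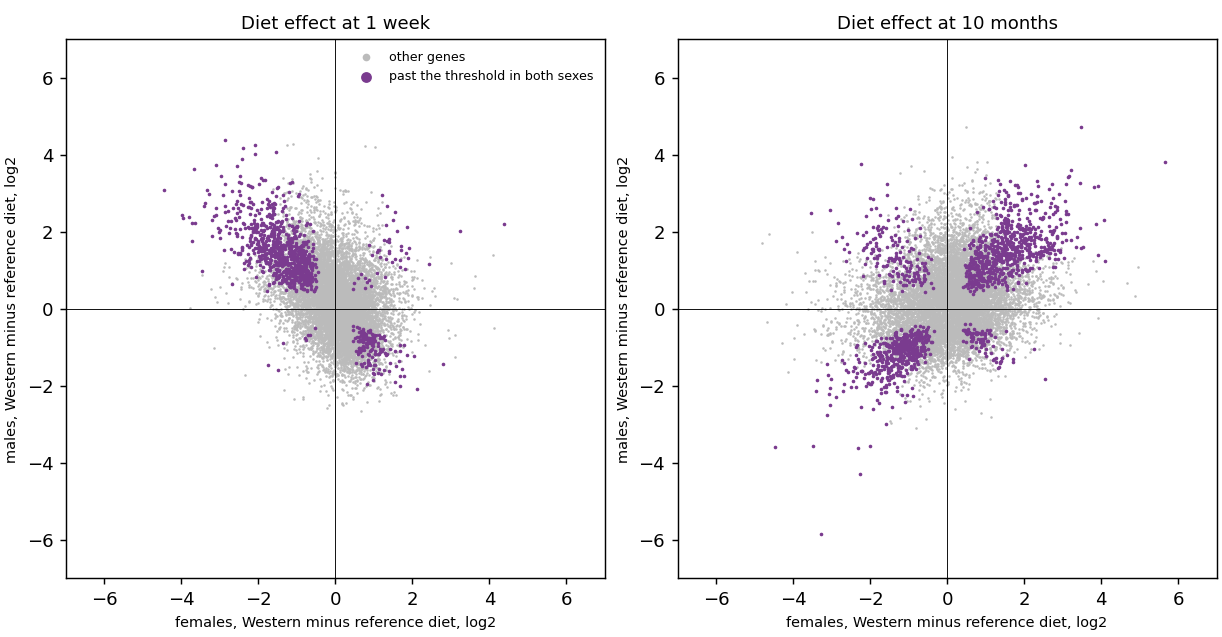
Diet effect (WD minus RD, log2) of each gene in females (horizontal) against males (vertical) at 1 week and at 10 months, with genes past the threshold in both sexes in purple. Pearson r was −0.44 at 1 week and 0.29 at 10 months.

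After 10 months on WD the female liver was compared with RD livers of the same duration. Limma camera passed 16 of 32 lists (10 higher, 6 lower), all lost with adjusted p = 0.0809 to 0.398 with an estimated correlation. Gpnmb (ENSMUSG00000029816, chromosome 6, 48986517 to 49020928) rose by 5.65 ± 0.78 (limma adjusted p = 1.6e-08), Lgals3 by 2.80 ± 0.33 and the lysosomal protease Ctsd by 2.06 ± 0.25; Trem2, the lipid receptor of scar-associated macrophages (ENSMUSG00000023992, chromosome 17, 48485726 to 48493472), rose by 2.74 ± 0.58 (limma adjusted p = 1.1e-04). Col1a1, the main fibrillar collagen (ENSMUSG00000001506, chromosome 11, 94797538 to 94814356), rose by 3.07 ± 0.64 (limma adjusted p = 7.6e-05), and the matrix genes Bgn by 1.95 ± 0.26, Timp2 by 1.94 ± 0.29 and Sparc by 1.64 ± 0.27, while the growth factor Ctgf fell (−4.63 ± 0.79). Arg1, the urea cycle arginase, fell (−1.65 ± 0.24), Tat, a tyrosine-degrading enzyme (−3.97 ± 0.64) and the urea cycle's Cps1 (−1.41 ± 0.30). Cd163, a scavenger receptor of resident macrophages, fell (−4.46 ± 0.6).

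Lipid-associated macrophage genes had 13 higher and 1 lower of 16 [13 and 2] with a level of 1.94, exact permutation adjusted p = 0.0123, and monocyte and macrophage genes 14 of 16 higher [15] with 1.77, exact permutation adjusted p = 0.0123; Cybb (2.16 ± 0.24), the complement gene C1qa (2.81 ± 0.31) and Aif1 (2.07 ± 0.26) led the latter, and Ctsl went the other way in the former (−1.41 ± 0.28). Collagen and matrix genes had 20 higher and 3 lower of 30 [20 and 3]; their level of 1.22, exact permutation adjusted p = 0.0495 lost its call without any 1 of 11 of the 12 animals, all but WD replicate 8 (adjusted p up to 0.102). Interferon genes had 7 of 17 higher [9] (level 1.04, exact permutation adjusted p = 0.0185), with Irf7 at 1.68 ± 0.25, Gbp2 at 3.15 ± 0.53 and Stat1 at 1.49 ± 0.30; T and NK cell markers had 5 of 10 higher [6] (level 1.30, exact permutation adjusted p = 0.0123), with Nkg7 at 2.16 ± 0.58, Cd8b1 at 1.95 ± 0.53 and Cd3d at 1.87 ± 0.56. LXR targets had 6 of 9 higher [7] (level 0.92, exact permutation adjusted p = 0.0123), led by the sterol carrier Npc2 (1.53 ± 0.20), Soat1 (1.57 ± 0.33) and Abca1 (1.08 ± 0.26). Oncofetal genes had 4 of 8 higher [4] (level 1.88, exact permutation adjusted p = 0.0123): the imprinted H19 was at 0 in every RD library and 3.02 to 6.5 on WD, and Anxa2 rose by 2.66 ± 0.35. Levels fell in fatty acid oxidation (−0.80, exact permutation adjusted p = 0.0123; 2 higher and 10 lower of 22 [2 and 10]; Acadl −1.33 ± 0.21, Ppara 1.22 ± 0.23), hepatocyte identity (−0.82, exact permutation adjusted p = 0.0123; 2 higher and 8 lower of 14 [2 and 8]), periportal genes (−0.65, exact permutation adjusted p = 0.0123; 1 higher and 5 lower of 12 [1 and 5]; Pck1 of gluconeogenesis −2.86 ± 0.55, Etnppl −1.82 ± 0.38), female-biased genes (−1.47, exact permutation adjusted p = 0.0287; 10 of 18 lower [10]; Sult3a1 −4.17 ± 0.52, Tox −1.42 ± 0.23, Fmo3 −3.13 ± 0.53) and ribosomal proteins (−1.02, exact permutation adjusted p = 0.0123; 4 of 7 lower [4]; Rps18 −1.71 ± 0.31).

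Kupffer cell markers had 6 higher and 1 lower of 9 [6 and 1] (Cd5l 2.53 ± 0.30, Vsig4 1.27 ± 0.25). Neutrophil markers had 5 higher and 1 lower of 7 [5 and 1] (S100a9 2.82 ± 0.64, S100a8 2.33 ± 0.54). Acute phase genes had 9 higher and 2 lower of 16 [10 and 3] (the iron hormone Hamp −2.42 ± 0.40, Saa2 3.87 ± 0.75, Orm3 2.1 ± 0.45). Chemokines had 6 higher and 2 lower of 17 [6 and 2] (Vcam1 1.86 ± 0.32, Cxcl9 1.68 ± 0.38). Cell cycle had 6 higher and 1 lower of 17 [6 and 1] (Cenpe at 0 in every RD library and 0 to 4.43 on WD, Top2a 2.75 ± 0.62). NRF2 genes had 6 of 13 higher [6] (Hmox1 1.46 ± 0.28, Gclm 0.84 ± 0.17). In lipid metabolism, fatty acid synthesis had 6 higher and 5 lower of 20 [6 and 5] (the desaturase Scd1 2.02 ± 0.34, Elovl5 −1.93 ± 0.35, Me1 −1.30 ± 0.29). Lipid droplet genes had 3 higher and 6 lower of 17 [3 and 6] (Plin3 1.35 ± 0.20, Apoa4 −2.61 ± 0.40). Bile acid genes had 4 higher and 5 lower of 15 [4 and 5] (the bile salt importer Slc10a1 −1.74 ± 0.28, Abcc2 1.19 ± 0.24, Cyp27a1 −1.65 ± 0.38). Cholesterol synthesis had 2 higher and 6 lower of 23 [2 and 6] (Ebp −1.45 ± 0.15, Hsd17b7 −1.88 ± 0.30). The unfolded protein response had 4 higher and 3 lower of 12 [4 and 3] (Herpud1 1.69 ± 0.20, Atf3 3.16 ± 0.59). The clock had 2 higher and 2 lower of 13 [2 and 2] (Arntl −3.53 ± 0.5, Tef 1.38 ± 0.20). Pericentral genes had 3 higher and 4 lower of 12 [3 and 5] (Rhbg 3.00 ± 0.47, Lect2 1.30 ± 0.22). Cholangiocyte markers had 3 of 10 higher [3] (Hnf1b 1.99 ± 0.36). B cell markers had 1 higher and 1 lower of 9 [1 and 1] (Cd22 1.81 ± 0.40, Ighm −2.37 ± 0.68). Endothelial markers had 3 higher and 4 lower of 14 [3 and 4]. Male-biased genes had 1 of 19 higher [1] (Selenbp2 2.16 ± 0.62). Stellate markers had 1 of 15 lower [1] (Rgs5 −0.94 ± 0.30). The mitochondrial genome had 2 higher and 5 lower of 9 [2 and 5]. With limma no erythrocyte marker passed (6 measured, 0 at unadjusted p under 0.05).

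The largest female rises without overlap were Gpnmb, the disintegrin Adam11 (4.10 ± 0.35) and 3 genes at 0 in every RD library: H19, B3gnt8 (3.83 to 6.13 on WD) and P2ry6 (3.63 to 5.88). The largest falls were the glutamate carrier Slc25a22 (−4.69 ± 0.73), Ctgf, Cd163, Sult3a1 and the lipase inhibitor G0s2 (−4.13 ± 0.77). Timp1, an inhibitor of matrix breakdown, was at 0 in every RD library and 0 to 4.97 on WD. Cyp7a1 (1.2 ± 0.39) lost its call without RD replicate 3 (0.92, adjusted p = 0.0958), as did Cd36 (0.84 ± 0.28; adjusted p = 0.0526), and Clec4f (0.68 ± 0.25) without RD replicate 3 or 4 or WD replicate 1 or 7 (adjusted p up to 0.0997). The others followed throughout did not pass: Ldlr −0.27 ± 0.39, Srebf1 −0.01 ± 0.74, Pcsk9 0.36 ± 0.66, Spp1 0.92 ± 0.66, Timd4 0.66 ± 0.46, Cidec −1.11 ± 0.55, Afp 0.42 ± 0.48 and Ly6d 0.76 ± 0.61. The markers Cela1 and Cfd stood at 0.74 ± 0.34 and −0.5 ± 0.91, neither passing. In all 4039 genes passed (1726 to 4504 under other settings; 2196 higher, 1843 lower; 1878 higher and 2100 lower after centring), 1109 without overlap. Camera calls were also lost with the mitochondrial genome mean as a covariate for Kupffer markers (adjusted p = 0.170), periportal genes (0.174), ribosomal proteins (0.297) and mitochondrial genome (0.760). Calls were lost with the ribosomal RNA covariate for Kupffer markers (0.0638) and NRF2 genes (0.0935), from rebuilt reads for NRF2 genes (0.0533), after centring for NRF2 genes (0.0560) and with a depth covariate for Kupffer markers (0.0554) and NRF2 genes (0.0554). Signs differed between camera and the members for fatty acid synthesis, B and plasma cell, male-biased and erythrocyte. Of 115 genes named by rule that passed, 101 also passed with reads drawn to equal depth, 89 with only the compared groups fitted, 102 with array weights and 112 with the mitochondrial ribosomal RNAs as a covariate; at equal depth Cd8b1, Cd3d, Selenbp2, Rgs5, Cd36 and Clec4f lost their calls. Level tests passed for 15 lists. The mitochondrial genome mean was 11.72 ± 0.05 on RD and 11.02 ± 0.37 on WD, and with it as a covariate 90 of the named genes passed. This mean was used as a stand-in for RNA quality, but it may also differ with the state of the liver.

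Males at 10 months followed. Limma camera passed 9 of 32 lists (4 higher, 5 lower), all lost with adjusted p = 0.141 to 0.511 with an estimated correlation. Gpnmb rose by 3.82 ± 0.78 (limma adjusted p = 6.3e-05), Trem2 by 2.01 ± 0.58, and Ms4a7, a membrane protein of recruited macrophages (ENSMUSG00000024672, chromosome 19, 11395529 to 11410636), by 3.74 ± 0.56; the elastase Mmp12 was at 0 in every RD library and at 2.39 to 5.85 on WD. Col1a1 rose by 2.80 ± 0.64 (limma adjusted p = 2.9e-04), with Col14a1 at 1.72 ± 0.25, Sparc at 1.75 ± 0.27 and the collagenase Mmp14 at 1.12 ± 0.23. Dhcr24, the last enzyme of cholesterol synthesis (ENSMUSG00000034926, chromosome 4, 106233643 to 106261718), rose by 3.94 ± 0.36, whereas Hsd17b7 (−1.64 ± 0.30), Cyp51 (−1.26 ± 0.33) and Pcsk9, which degrades the LDL receptor (−2.12 ± 0.66), fell. Cd36, a fatty acid importer (ENSMUSG00000002944, chromosome 5, 17287508 to 17394777), rose by 1.86 ± 0.28 (limma adjusted p = 1.0e-07). Cyp7a1 rose by 1.51 ± 0.39.

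Lipid-associated macrophage genes had 11 higher and 0 lower of 16 [12 and 1] with a level of 1.65, exact permutation adjusted p = 0.0123, adding Lpl at 2.06 ± 0.31; LXR targets had 5 higher and 1 lower of 9 [7 and 1] with 0.98, exact permutation adjusted p = 0.0123, led by Soat1 (2.29 ± 0.33) and Abca1 (1.21 ± 0.26), and endothelial markers had 1 higher and 5 lower of 14 [1 and 5] with −0.47, exact permutation adjusted p = 0.0123, led by Kdr (−0.78 ± 0.15) and Clec4g (−0.86 ± 0.21). Monocyte and macrophage genes had 10 of 16 higher [11], with Mpeg1 at 2.95 ± 0.37, Cybb at 1.68 ± 0.24 and Fcgr3 at 0.86 ± 0.21; their level of 1.02, exact permutation adjusted p = 0.0185 lost its call without any 1 RD animal (adjusted p up to 0.0633). Collagen and matrix genes had 19 of 30 higher [20], and their level of 1.31, exact permutation adjusted p = 0.0287 lost its call without RD replicate 1, 2 or 3 or WD replicate 3 (adjusted p up to 0.0633). Fatty acid oxidation had 4 higher and 10 lower of 22 [4 and 10], with the hydroxylase Cyp4a14 at −3.56 ± 0.55, Ppara at 1.44 ± 0.23 and Acadm at 1.5 ± 0.25; NRF2 genes had 7 higher and 0 lower of 13 [7 and 1], with Gclm at 1.39 ± 0.17, Gclc at 1.64 ± 0.26 and Txnrd1 at 1.42 ± 0.26. Male-biased genes had 2 higher and 8 lower of 19 [2 and 9], with Ugt2b1 at 1.49 ± 0.26, Cyp7b1 at −2.18 ± 0.39 and Elovl3 at −2.35 ± 0.55, and female-biased genes 2 of 18 lower [1], with Cyp2b13 at −2.70 ± 0.55.

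Bile acid genes had 4 higher and 4 lower of 15 [6 and 4] (Cyp8b1 −2.14 ± 0.36, Slco1b2 1.01 ± 0.19, Abcc2 1.22 ± 0.24). Cholesterol synthesis had 2 higher and 5 lower of 23 [2 and 5]. Fatty acid synthesis had 3 higher and 6 lower of 20 [3 and 6] (Lpin1 −1.85 ± 0.41, the glucose kinase Gck 2.68 ± 0.72). Lipid droplet genes had 3 higher and 3 lower of 17 [3 and 3] (Pnpla2 −1.38 ± 0.19, Plin5 −1.53 ± 0.27). Acute phase genes had 7 higher and 1 lower of 16 [8 and 2] (the iron carrier Lcn2 3.24 ± 0.68, Hpx 1.07 ± 0.23, Orm3 1.82 ± 0.45). Chemokines had 4 of 17 higher [4] (Cxcl9 1.42 ± 0.38, Cxcl1 3.27 ± 0.91). Cell cycle genes had 5 of 17 higher [5] (Birc5 1.94 ± 0.39). Cholangiocyte markers had 6 of 10 higher [7] (Bicc1 1.68 ± 0.35). Stellate markers had 4 higher and 1 lower of 15 [4 and 1] (Dcn 1.31 ± 0.21). Neutrophil markers had 4 of 7 higher [4]. Kupffer markers had 2 higher and 1 lower of 9 [2 and 2] (Cd163 −3.58 ± 0.6, Cd5l 1.60 ± 0.30). Interferon genes had 4 higher and 1 lower of 17 [4 and 1] (Ifit2 2.49 ± 0.58). Unfolded protein response had 2 higher and 1 lower of 12 [2 and 1] (Pdia4 2.52 ± 0.31). Oncofetal genes had 2 higher and 1 lower of 8 [2 and 1] (Anxa2 1.55 ± 0.35, Tff3 −2.81 ± 0.65). The hepatocyte identity list had 2 higher and 2 lower of 14 [2 and 2] (Rgn 0.91 ± 0.20). Periportal genes had 1 higher and 4 lower of 12 [1 and 5] (Etnppl −1.80 ± 0.38, Gls2 −1.03 ± 0.29). Pericentral genes had 2 higher and 1 lower of 12 [2 and 1] (Glul 0.65 ± 0.15, Oat −1.05 ± 0.29); erythrocyte genes had 3 of 6 lower [5] (the paralogs Hbb-b1 −1.52 ± 0.34 and Hbb-bt −1.26 ± 0.34). The clock had 1 higher and 1 lower of 13 [1 and 1] (Per1 −2.16 ± 0.39). Ribosomal proteins had 1 of 7 lower [1]. With limma no member passed among T and NK cell markers (10 measured, 0 at unadjusted p under 0.05), B and plasma cell markers (9, 1) and mitochondrial genome (9, 3).

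The largest male changes without overlap were Dhcr24, Bccip (3.83 ± 0.51), Ms4a7, Snx9 (3.71 ± 0.46) and Mmp12 upwards, and Ppp1r3g (−5.84 ± 0.80), the insulin-suppressed Igfbp1 (−3.62 ± 0.47), Cd163, Cyp4a14 and Psg23 (−3.08 ± 0.58) downwards. Ldlr (−1.08 ± 0.39) and Spp1, osteopontin (2.25 ± 0.66), lost their calls without RD replicates 1 or 2 (adjusted p up to 0.0789) and 2 or 4 (up to 0.0590). Timp1 and Afp were at 0 in every RD library and at 0 to 2.96 and 0 to 1.82 on WD, with calls lost without RD replicate 1, 2, 3 or 4 or WD replicate 1, 2, 3, 6 or 8 (adjusted p up to 0.0845) and without RD replicate 1, 2, 3 or 4 or WD replicate 1, 2, 4, 5, 6 or 8 (up to 0.0875). The others followed throughout did not pass: Srebf1 0.25 ± 0.74, Clec4f −0.43 ± 0.25, Timd4 −0.29 ± 0.46, Cidec −1.28 ± 0.55 and Ly6d 0.96 ± 0.61. Cela1 (−0.51 ± 0.34) did not pass, and Cfd (2.08 ± 0.91) only without RD replicate 2 or WD replicate 4 or 5 (adjusted p down to 0.0233). In all 3696 genes passed (2393 to 4407 under other settings; 2378 higher, 1318 lower; 1740 higher and 1996 lower after centring, 1944 higher and 560 lower at equal depth, 3518 higher and 889 lower from rebuilt reads), 1780 without overlap. Camera calls were also lost from rebuilt reads for NRF2 genes (adjusted p = 0.110). Calls were lost after centring for NRF2 genes (0.0586) and with a depth covariate for male-biased genes (0.227) and NRF2 genes (0.0695). Signs differed between camera and the members for lipid droplet, bile acid, stellate cell, T and NK cell, unfolded protein response and circadian clock. Of 106 genes named by rule that passed, 90 also passed with reads drawn to equal depth, 93 with only the compared groups fitted, 99 with array weights and 87 with the mitochondrial ribosomal RNAs as a covariate; at equal depth Pcsk9, Clec4g, Gck, Birc5, Ldlr and Afp lost their calls. Level tests, with the same limit as at 1 week, passed for 10 lists, and for 3, 5 and 4 without RD replicate 1, 2 and 3.

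The 10-month diet effect was compared between the sexes in the same way. Ctgf, which promotes fibrosis (ENSMUSG00000019997, chromosome 10, 24315248 to 24318489), had the largest positive difference, male minus female, at 6.58 ± 1.12 (limma adjusted p = 6.8e-06), followed by the phosphate carrier Slc20a2 (6.52 ± 1.17), the ubiquitin ligase Syvn1 (6.02 ± 1.09) and the splicing factor Snrnp70 (5.62 ± 0.70). B3gnt8, a sugar-chain enzyme (ENSMUSG00000059479, chromosome 7, 26412643 to 26414509), led the negative differences at −4.54 ± 0.76, with Trmt12 (−4.37 ± 0.6), Gpr137b (−4.18 ± 0.67) and Pdlim7 (−4.11 ± 0.74). Camera passed monocyte and macrophage genes (1 higher and 3 lower of 16 [1 and 3]). It also passed male-biased genes (1 higher and 4 lower of 19 [1 and 4]). Both had camera adjusted p = 0.0492, and adjusted p = 0.673 with an estimated correlation. Females and males shared 721 higher and 475 lower genes (458 and 213 expected), with 264 opposite (638 expected) and r = 0.29 across genes. In all 2651 differences passed (1356 to 3337 under other settings; 1497 positive, 1154 negative; 1276 positive and 1381 negative after centring, 979 positive and 401 negative at equal depth and 2032 positive and 871 negative from rebuilt reads).

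The 10-month diet effect minus the 1-week effect was tested within each sex. In females Ugt1a5 (6.66 ± 0.86), Gprin3 (6.35 ± 0.72), the BMP receptor Bmpr2 (5.61 ± 0.67) and the growth factor Btc (ENSMUSG00000082361, chromosome 5, 91786287 to 91831939; 5.59 ± 0.75) moved up the most, and Ctgf (−6.09 ± 1.12), Sult3a1 (−5.69 ± 0.74), Cyp3a44 (−5.51 ± 0.87) and Serpina1e (−5.32 ± 0.96) down. Hepatocyte identity (8 of 14 lower [8]) and periportal genes (7 of 12 lower [8]) shifted down, both at camera adjusted p = 8.5e-04. So did female-biased genes (0 higher and 8 lower of 18 [1 and 9], camera adjusted p = 0.00645). With an estimated correlation camera gave adjusted p = 0.196, 0.196 and 0.583. In males Gpnmb (4.50 ± 1.11; limma adjusted p = 0.00852), Ttc39a (4.06 ± 0.81), Mmp12 (4.03 ± 1.00) and Cidea, a lipid droplet fusion protein (ENSMUSG00000024526, chromosome 18, 67503218 to 67527448; 3.89 ± 1.03), moved up, and Ppp1r3g (−5.87 ± 1.13), Hsd3b5 (−5.02 ± 0.91), Plk3 (−4.82 ± 0.85) and Mup1 (−4.77 ± 1.06) down. Male-biased genes (7 of 19 lower [10]) and endothelial markers (1 of 14 lower [6]) held, each at camera adjusted p = 0.0250 with an estimated correlation. Female effects at these durations correlated at r = −0.09 across genes (218 higher and 73 lower in both, 127 and 200 expected; 425 opposite, 344 expected). Male effects were alike (r = 0.54; 1297 higher and 523 lower in both, 493 and 136 expected). In females 3603 differences passed (1427 to 4121 under other settings; 2031 positive, 1572 negative; 1536 positive and 2005 negative after centring), and in males 505 (251 and 254; 255 positive and 166 negative from rebuilt reads), or 243 without male RD replicate 2 of 1 week and 181 with only the 4 compared groups in the fit.

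Within WD animals each duration was compared with 1 week (n = 8 against 8, where 0.0155% of genes are expected without overlap by chance). Mean Gpnmb in males was 0.75, 1.74, 1.93, 5.85 and 5.19 at the 5 durations, Trem2 1.73, 2.59, 2.31, 4.47 and 5.13, and Col1a1 3.39, 3.77, 2.74, 5.76 and 5.64. Cidea rose the most by 10 months, by 7.86 ± 0.59 (limma adjusted p = 2.0e-19), with means of 1.94 at 2 months and 6.90 at 5 months; Lcn2 (ENSMUSG00000026822, chromosome 2, 32240153 to 32243317) rose by 4.70 ± 0.55, Gpnmb by 4.44 ± 0.64, the surface protein Ly6d (ENSMUSG00000034634, chromosome 15, 74592486 to 74593997) by 4.11 ± 0.5 and the interferon-induced Ifi27l2b by 3.80 ± 0.37. Hsd3b5 (−4.22 ± 0.53), the organic anion carrier Slco1a1 (−3.83 ± 0.49), Mup1 (−3.74 ± 0.61), Serpina1e (−3.45 ± 0.56) and Mup7 (−3.43 ± 0.6) fell the most. The level of lipid-associated macrophage genes was −1.12, −0.84, −0.95, 0.70 and 0.51. At 5 months 12 higher and 0 lower of 16 [13 and 1] of that list passed (camera adjusted p = 0.00280 with an estimated correlation), with monocyte genes 13 of 16 higher [15] (adjusted p = 0.00331 with an estimated correlation). Chemokines had 11 of 17 higher [14] (adjusted p = 0.0164 with an estimated correlation). NRF2 genes had 10 higher and 0 lower of 13 [10 and 1] (adjusted p = 0.0138 with an estimated correlation).

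By 10 months male monocyte genes had 14 of 16 higher [15] (adjusted p = 0.00177 with an estimated correlation). Lipid-associated macrophage genes had 12 higher and 1 lower of 16 [12 and 1] (adjusted p = 0.00347 with an estimated correlation). Collagen and matrix genes had 13 of 30 higher [20] (adjusted p = 0.0324 with an estimated correlation). Lipid droplet genes had 8 higher and 1 lower of 17 [9 and 1] (adjusted p = 0.0223 with an estimated correlation). Male-biased genes had 12 of 19 lower [12] (adjusted p = 0.0114 with an estimated correlation). Periportal genes had 0 higher and 8 lower of 12 [1 and 8] (adjusted p = 0.00799 with an estimated correlation). Hepatocyte identity genes had 8 of 14 lower [9] (adjusted p = 0.0283 with an estimated correlation). Earlier, at 1 month, fatty acid oxidation genes had 14 of 22 lower [18] in males (adjusted p = 1.6e-04 with an estimated correlation). Male counts, each with its range under other settings, were 610 (453 to 1688; 317 higher, 293 lower) at 1 month, 526 (314 to 1423; 307, 219; 342 higher and 373 lower from rebuilt reads) at 2 months, 2488 (1654 to 4204; 1263, 1225; 1239 higher and 1299 lower after centring) at 5 months and 1708 (1199 to 2808; 1005, 703) at 10 months, of which 145, 143, 350 and 324 showed no overlap. In single livers, male replicate 1 at 1 month had cholesterol synthesis at 2.36, fatty acid synthesis at 2.20 and Pcsk9 at 5.75, far above its group, and male replicate 3 at 5 months had Gpnmb at only 1.45, Clec4f at 7.03 and neutrophil genes at 2.46.

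**Figure D3:**
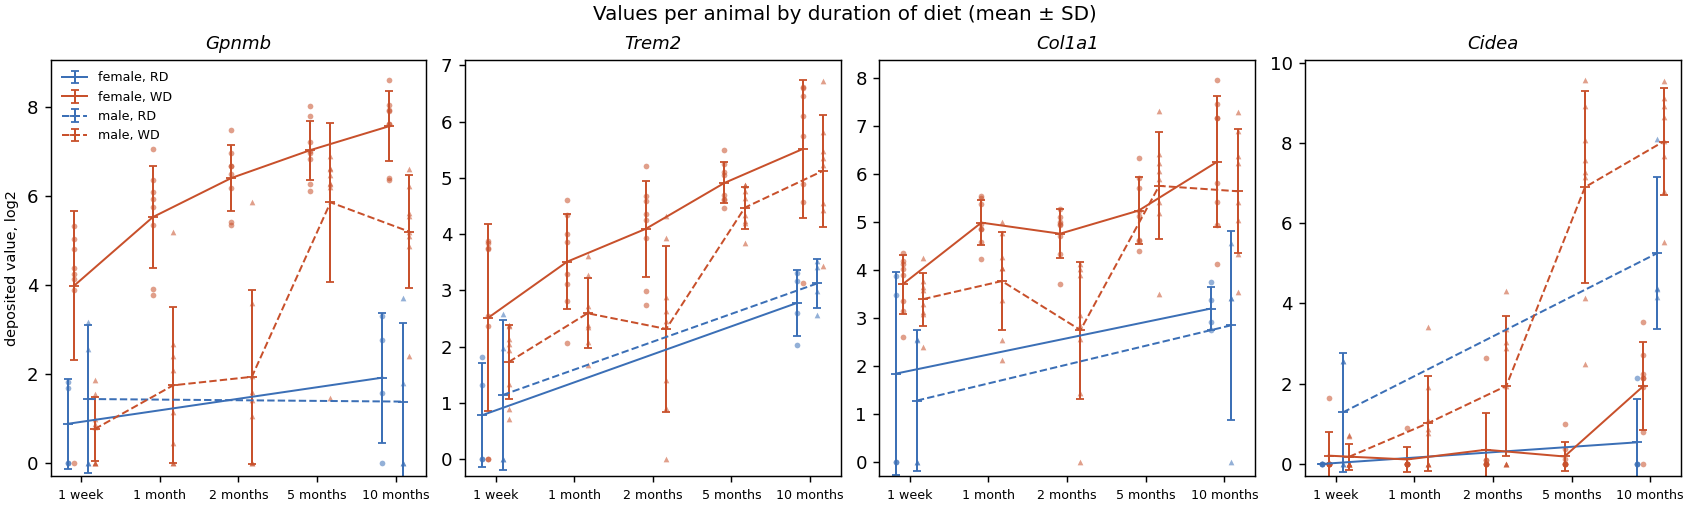
Values (log2) of Gpnmb, Trem2, Col1a1 and Cidea in each animal by duration, females as circles with solid lines and males as triangles with dashed lines, RD blue and WD red, with mean ± SD. Mean Gpnmb in WD males was 1.93 at 2 months and 5.85 at 5 months.

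In females mean Gpnmb was 3.98, 5.52, 6.4, 7.02 and 7.56 at the 5 durations, Trem2 2.51, 3.51, 4.09, 4.91 and 5.51, and Col1a1 3.70, 4.99, 4.76, 5.24 and 6.26, while the Kupffer receptor Cd163 went 5.64, 3.52, 2.88, 2.28 and 0.49. By 10 months the motor protein Myo5a (ENSMUSG00000034593, chromosome 9, 74918822 to 75071495) had risen by 3.62 ± 0.48 (limma adjusted p = 1.5e-09), Gpnmb by 3.58 ± 0.64, the detoxifying Gstm3 by 3.58 ± 0.63, Lgals1 by 3.56 ± 0.35 and the protease Htra1 by 3.55 ± 0.45. Cd163 (ENSMUSG00000008845, chromosome 6, 124254669 to 124280545) had fallen (−5.16 ± 0.49, limma adjusted p = 5.5e-15), Unc50 (−4.36 ± 0.76), Slc25a22 (−4.07 ± 0.59), Tns2 (−4.0 ± 0.47) and Slc20a2 (−3.94 ± 0.67). The level of lipid-associated macrophage genes was −0.01, 0.59, 0.70, 1.02 and 1.52. At 1 month fatty acid oxidation genes had 17 of 22 lower [18] (adjusted p = 0.00348 with an estimated correlation). Lipid droplet genes had 1 higher and 9 lower of 17 [1 and 10] (adjusted p = 0.0112 with an estimated correlation). NRF2 genes had 6 of 13 higher [7] (adjusted p = 0.0213 with an estimated correlation). At 10 months periportal genes had 9 of 12 lower [9] (adjusted p = 0.0496 with an estimated correlation). Monocyte genes had 12 of 16 higher [12] (camera adjusted p = 2.6e-07). Hepatocyte identity genes had 0 higher and 11 lower of 14 [1 and 11] (camera adjusted p = 6.5e-05). Collagen genes had 17 higher and 2 lower of 30 [18 and 2] (camera adjusted p = 1.9e-04). With an estimated correlation camera gave adjusted p = 0.0820, 0.0820 and 0.284. At 1 week female replicate 8 differed from the other 7 animals: its acute phase level was −0.58, its Gpnmb 0 and its Ldlr 6.79.

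Female counts, with the same ranges, were 2104 (1343 to 2831; 1281 higher, 823 lower; 868 higher and 1160 lower after centring) at 1 month, 4823 (3310 to 5463; 2766, 2057; 2204 higher and 2428 lower after centring) at 2 months, 4405 (3099 to 5042; 2521, 1884; 1856 higher and 2376 lower after centring) at 5 months and 4887 (3001 to 5246; 2519, 2368; 2422 higher and 2437 lower after centring) at 10 months, of which 402, 1728, 980 and 857 showed no overlap. An F test over the 5 durations passed 7061 genes in females and 3477 in males. Females and males shared 611 higher and 298 lower genes between 1 week and 10 months of WD (222 and 146 expected; r = 0.36), among them Gpnmb upwards. Without RD animals at 1, 2 and 5 months, aging and diet cannot be separated along this course.

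**Figure D4:**
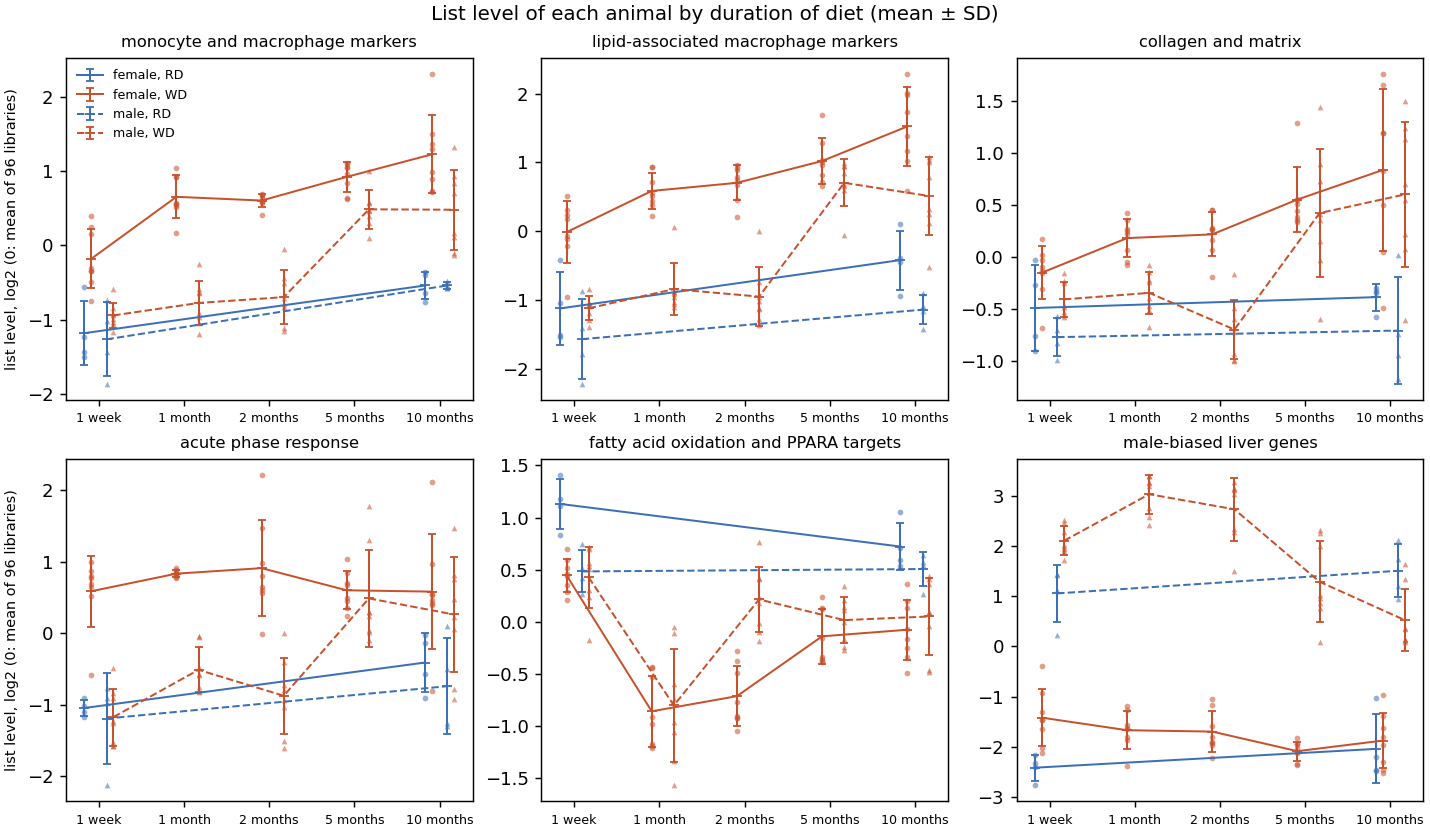
Level of 6 gene lists in each animal (log2 deviation from the mean of 96 libraries) by duration, sex and diet, with mean ± SD. The lipid-associated macrophage level of WD females was −0.01 at 1 week and 1.52 at 10 months.

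RD animals were compared at 10 months against 1 week (n = 4 against 4, where 2.86% of genes are expected without overlap by chance). In females Jchain, which joins antibody chains (ENSMUSG00000067149, chromosome 5, 88949537 to 88956916), was at 0 at 1 week and 2.76 to 5.75 at 10 months, Ighm, the IgM heavy chain (ENSMUSG00000076617, chromosome 12, 114659078 to 114660941), rose by 3.94 ± 0.79 (limma adjusted p = 3.3e-04), Cyp3a44 by 3.53 ± 0.71 and the early-response Nr4a1 by 3.01 ± 0.51. Gprin3 (−4.16 ± 0.58), Ilf2 (−3.53 ± 0.52) and Ugt1a5 (−3.31 ± 0.70) fell, and Scara3 was at 2.49 to 3.71 at 1 week and at 0 in every 10-month library. In males Cidea rose by 3.97 ± 0.84 (limma adjusted p = 0.00147), as it did on WD, with Ifi27l2b at 3.54 ± 0.53 and Jchain at 3.31 ± 0.70; Ddit3 was at 0 at 1 week and 3.12 to 3.71 at 10 months. Ajuba fell (−3.27 ± 0.59), and Snx14 (2.56 to 4.30 at 1 week), Hsf1 (2.54 to 3.74) and Ap5m1 (2.56 to 3.74) were at 0 in every 10-month library. Monocyte genes had 4 of 16 higher [7] in females (camera adjusted p = 1.2e-04) and 2 of 16 [2] in males (adjusted p = 0.00221). Unfolded protein response genes had 4 of 12 higher [5] in males (camera adjusted p = 0.00221). With an estimated correlation camera gave adjusted p = 0.479, 0.363 and 0.118. In females 892 genes passed (183 higher, 709 lower, 559 without overlap), or 483 without RD replicate 2 of 10 months. After centring 359 were higher and 406 lower, and at equal depth 52 and 225. The count also fell with the mitochondrial ribosomal RNA covariate or only these groups fitted. Female depth fell too (median 1.11 to 0.451 M reads), so falls may be partly depth. In males 656 passed (413 higher, 243 lower, 227 without overlap), or 223 without RD replicate 2 of 1 week and 12 with only these groups in the fit. RD and WD changes over the same months correlated at r = −0.21 in females and 0.19 in males, and those of the sexes on RD at r = −0.02.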

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

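Tests of mitochondrial ribosomal RNA, hepatocyte share, RNA quality as a source of spread within groups and other splits were chosen after the results were seen. In 56 of 667 groups of 4 or 8, 1 library lay far from the others by Dixon's criterion, which by chance picks about 1 group in 20. Where the others are all 0, 1 read is enough, as for Pcsk9 at 1.57 and Timp1 at 1.59, 0.98 and 0.70. Srebf1 at 1.12 is 1 read too. For depth (M reads) these were female WD 1 week replicate 7 at 1.32 and male RD 10 months replicate 4 at 0.675. List levels (log2) far above the group were cholesterol synthesis (female RD 10 months replicate 1 at −0.25, male WD 1 month replicate 1 at 2.36), fatty acid synthesis (male RD 1 week replicate 2 at 0.25, male WD 1 month replicate 1 at 2.20), collagen and matrix (female WD 5 months replicate 8 at 1.29), Kupffer (female WD 10 months replicate 7 at 1.79), lipid-associated macrophage (male WD 1 month replicate 4 at 0.067, male WD 2 months replicate 7 at 0.0034), neutrophil (male WD 5 months replicate 3 at 2.46), B cell (female WD 10 months replicate 5 at 3.50), cholangiocyte (male WD 5 months replicate 2 at 1.62), endothelial (female RD 1 week replicate 2 at 0.11), hepatocyte identity (male RD 1 week replicate 1 at 0.40), pericentral (male WD 5 months replicate 1 at 0.69), cell cycle (female WD 10 months replicate 7 at 1.72), unfolded protein response (male WD 2 months replicate 8 at 0.74), circadian clock (female RD 10 months replicate 1 at 0.23, male WD 1 month replicate 7 at 0.46). Levels far below it were lipid droplet (female WD 1 month replicate 4 at −1.24), collagen and matrix (female RD 10 months replicate 1 at −0.58), Kupffer (male RD 1 week replicate 2 at −1.08), lipid-associated macrophage (male WD 5 months replicate 3 at −0.058), monocyte (female WD 2 months replicate 7 at 0.41), cholangiocyte (female WD 1 month replicate 8 at −0.85), endothelial (male WD 10 months replicate 4 at −0.78), hepatocyte identity (male WD 5 months replicate 2 at −0.80), pericentral (male RD 10 months replicate 1 at −0.86), acute phase response (female WD 1 week replicate 8 at −0.58, male RD 1 week replicate 2 at −2.13), cell cycle (female WD 1 month replicate 8 at −1.10), mitochondrial genome (female RD 10 months replicate 2 at 0.28). Single genes (log2) far above were Ldlr (female WD 1 week replicate 8 at 6.79), Pcsk9 (female RD 10 months replicate 1 at 1.57, male WD 1 month replicate 1 at 5.75), Timp1 (female RD 1 week replicate 4 at 1.44, female WD 1 week replicate 4 at 1.59, male WD 1 week replicate 4 at 0.98, male WD 1 month replicate 4 at 0.70), Spp1 (female WD 5 months replicate 8 at 5.11), Clec4f (female WD 1 month replicate 1 at 7.34, male WD 5 months replicate 3 at 7.03). Genes far below were Ldlr (female WD 1 month replicate 8 at 0), Cyp7a1 (female WD 1 month replicate 2 at 6.76, male WD 2 months replicate 2 at 6.33), Srebf1 (male WD 5 months replicate 6 at 1.12), Gpnmb (female WD 1 week replicate 8 at 0, male WD 5 months replicate 3 at 1.45, male WD 10 months replicate 5 at 2.39), Spp1 (female WD 2 months replicate 3 at 0, male WD 1 month replicate 5 at 0), Timd4 (male WD 1 month replicate 5 at 1.99), Cidec (female RD 10 months replicate 4 at 6.22, male RD 1 week replicate 2 at 5.47), Ly6d (female WD 1 month replicate 8 at 0).

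The diet effect differed between groups, by limma's test of the difference, for the results below (log2). Between the sexes at 1 week, male minus female, these were 4004 genes in all, Cdc42bpb 6.43, Cyp2b10 −4.35, Cyp2c54 −4.61, Ilf2 6.58, Nxt1 −4.20, Orm3 −4.23, Tec 6.43, Ugt1a5 7.54, Gpnmb −3.78, Clec4f −0.93 and the acute phase response list (mean −1.61). At 10 months they were 2651 genes in all, B3gnt8 −4.54, Ctgf 6.58, Gpr137b −4.18, Pdlim7 −4.11, Slc20a2 6.52, Snrnp70 5.62, Syvn1 6.02, Trmt12 −4.37, Pcsk9 −2.47, Clec4f −1.11, the monocyte and macrophage markers list (mean −0.75) and the male-biased liver genes list (mean −1.15). Between 10 months and 1 week in females they were 3603 genes in all, Bmpr2 5.61, Btc 5.59, Ctgf −6.09, Cyp3a44 −5.51, Gprin3 6.35, Serpina1e −5.32, Sult3a1 −5.69, Ugt1a5 6.66, Timp1 2.23, Cd36 1.42, the hepatocyte identity list (mean −1.2), the periportal hepatocyte genes list (mean −1.28) and the female-biased liver genes list (mean −1.46); in males they were 505 genes in all, Cidea 3.89, Gpnmb 4.50, Hsd3b5 −5.02, Mmp12 4.03, Mup1 −4.77, Plk3 −4.82, Ppp1r3g −5.87, Ttc39a 4.06, Cd36 1.63, the cholesterol synthesis list (mean −0.54), the collagen and matrix list (mean 0.95), the lipid-associated macrophage markers list (mean 1.2), the monocyte and macrophage markers list (mean 0.70), the neutrophil markers list (mean 1.28), the cholangiocyte markers list (mean 0.82), the sinusoidal endothelial markers list (mean −0.76), the male-biased liver genes list (mean −2.03), the chemokines and inflammatory signalling list (mean 0.67), the acute phase response list (mean 0.98), the NRF2 and glutathione list (mean 0.79) and the erythrocyte markers list (mean −1.47). The lists passed in limma camera with the preset correlation; the male-biased and endothelial lists of the male time difference kept adjusted p = 0.0250 with an estimated correlation. The others were lost, with adjusted p = 0.187 to 0.946 with an estimated correlation.

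The first pattern was the opposite sign of the 1-week diet effects in females and males, seen for Ppara and Ugt1a5 and for Pdia4, whose female estimate turned to 0.31 with the mitochondrial ribosomal RNA covariate. The tables argue against depth as the whole cause: with reads drawn to equal depth the effects still correlated at r = −0.471. The content of mitochondrial ribosomal RNA stayed open, since across genes the female effect correlated at r = −0.415 and the male effect at 0.431 with the slope on these RNAs within groups, beyond the largest of 100 shuffles (0.333 and 0.347). With these RNAs as a covariate the correlation between the sexes was −0.255, 112 genes passed in females (median SE 0.626 in place of 0.422), and the call of most genes ended through smaller estimates as well as wider errors (median size of the estimates of the called genes 0.610 in place of 1.27). A true sex difference in the early response to the diet stays open beside it, as untested, because RNA composition went with the groups.

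The second pattern was the higher level of 62 macrophage and matrix genes at 10 months, such as Gpnmb and Col1a1, with a median of 1.87 in females and 1.26 in males. The tables argue against depth: the median with thinned reads over that with rebuilt reads was 1.000 in females and 0.979 in males. They argue against RNA quality as the whole cause, as far as the mitochondrial genome level stands for it. With this level as a covariate the median was 0.844 of its size in females and 0.988 in males. A lower share of hepatocytes was not decided, as endothelial levels fell in males (−0.47). Their gap to macrophage levels grew by 2.01 in females and 1.81 in males (exact permutation p = 0.00202 each). Matrix genes were not tested. No test separated a gain of macrophages from a change of their state, so both stay open as hypotheses found on the same data.

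The third pattern was a spread within groups, whose first component held 12.4% of the residual variance. It went with the mitochondrial genome level over 96 libraries (r = −0.848, permutation p = 1.0e-05, the smallest possible with 100000 permutations). Without the 2 farthest libraries r was −0.839. RNA quality stays an open source of this spread, with the mitochondrial genome level as its only stand-in. The tables argue against transcript length (rho = 0.0709 across protein-coding genes), and GC content could not be decided (rho = 0.174, between the limits set in advance). The component's loading correlated with the 10-month diet effect at 0.60 in females and 0.209 in males. No biological explanation was tested for it.

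Other splits of the same libraries into groups of the same sizes were refitted, 100 per comparison with the real one included. In each comparison named next, 1 of 100 splits, the real one, gave the highest count. For each on its own, this argues against a chance division of the animals, except for the sex and time differences. Counts and highest other splits were 1896 against 594 (diet at 1 week, females), 3539 against 1721 (males), 4039 against 2054 (10 months, females) and 3696 against 1984 (males), 4004 against 2452 (sex difference at 1 week), 3603 against 881 and 505 against 345 (time differences, females and males) and 3798 against 2558 (sex in RD). For WD against 1 week they were 2104 against 1507, 4823 against 2145, 4405 against 3528 and 4887 against 2473 in females and 610 against 146, 526 against 9, 2488 against 1317 and 1708 against 1336 in males, and over 5 durations 7061 against 1536 and 3477 against 343. For RD over time 1 of all 35 splits, the real one, was the highest (892 against 548 in females, 656 against 410 in males). The sex difference at 10 months was reached by 2 of 100 splits, the real one included, and 1 other split gave more (2651 against 2884). For passing lists chance was not excluded. In females at 1 week the real split led (1 of 100, 13 lists against 11). At 10 months it did not in females (8 of 100, 16 against 19) or males (33 of 100, 9 against 19). In males at 1 week 0 lists passed in limma camera (4 at unadjusted p under 0.05), a count that 100 of 100 splits reach by necessity (0 against 4), so it says nothing about chance.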

How the results depend on the processing

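The settings with reads at equal depth, rebuilt reads, depth, mitochondrial or residual covariates, and without shallow libraries were chosen after the results were seen; the others, and each library left out in turn, were set in advance. All of these were run. Of 8520 gene results under other settings 7775 kept direction and side of the threshold, 613 weakened, 128 strengthened and 4 reversed; with 1 library left out these were 7061, 260, 58 and 1 of 7380. Of list tests 924 of 1024 kept theirs (1 reversed), and 1475 of 1536 with 1 library left out; of list levels 112 of 128 and 1420 of 1536. Of counts, 281 of 351 stayed within 1.5 times, and 468 of 480 with 1 library left out. Signs reversed in females at 1 week with the mitochondrial ribosomal RNA covariate for Cps1 (0.62), Ifit2 (0.58), Pdia4 (0.31) and Txnrd1 (0.36) and, for the list mitochondrial genome with its own mean as covariate, in camera (adjusted p = 0.878), and in males for Pecam1 (−0.69 without RD replicate 2 of 1 week; −0.69 to 1.62 over all single omissions). Counts that moved follow (F females, M males). For these and the reversals the cause was not tested, except that settings in brackets left out genes or libraries. With reads drawn to equal depth: diet 1 week F 1090, diet 1 week M 2140, diet 10 months F 2495, sex difference 10 months 1380, time difference F 2230, time difference M 103, WD 1 month F 1373, RD 10 months F 277, RD 10 months M 81, sex in RD 2485, lists in diet 1 week M 4. With these as log2(reads + 1): diet 1 week F 1062, diet 1 week M 2141, diet 10 months F 2464, sex difference 1 week 2642, sex difference 10 months 1356, time difference F 2177, time difference M 97, WD 1 month F 1343, WD 2 months M 314, WD 5 months M 1654, RD 10 months F 263, RD 10 months M 88, sex in RD 2470. With the mitochondrial genome covariate: diet 1 week F 3742, diet 10 months F 1869, time difference M 844. With the mitochondrial ribosomal RNA covariate: diet 1 week F 112, diet 1 week M 1705, diet 10 months M 2393, sex difference 1 week 320, time difference F 1427, WD 10 months F 3001, RD 10 months F 289, lists in diet 1 week M 4, lists in diet 10 months M 16. With array weights: diet 10 months F 2412, sex difference 10 months 1729, time difference M 129, WD 1 month M 1688, WD 2 months M 1423, WD 5 months M 4204, WD 10 months M 2808, RD 10 months M 28, WD durations M 6105. With only the compared groups fitted: diet 10 months F 1726, sex difference 10 months 1527, time difference M 181, WD 1 month M 1137, WD 2 months M 1057, RD 10 months F 236, RD 10 months M 12, sex in RD 2482. With genes above the median mean (fewer genes tested): time difference M 331, RD 10 months M 420, WD durations F 4694. With the first residual component as covariate: time difference M 859, WD 1 month M 1009, WD 2 months M 869, RD 10 months F 1381, RD 10 months M 1108. Without libraries under 0.4 M reads (fewer libraries): time difference M 794, RD 10 months F 538. With rebuilt reads: RD 10 months M 371, lists in diet 1 week M 3. With an estimated correlation: lists in diet 1 week F 0, lists in diet 10 months F 0, lists in diet 10 months M 0. With centred libraries: lists in diet 1 week M 3. With a depth covariate: lists in diet 1 week M 1. With each library left out in turn: time difference M 243 to 699, RD 10 months F 483 to 1125, RD 10 months M 223 to 903, lists in diet 1 week M 0 to 4, levels in diet 1 week F 8 to 14, levels in diet 1 week M 5 to 11, levels in diet 10 months M 3 to 12. In simulations drawn at each library's estimated depth, changed genes were taken from those with a mean of at least 5 RPM. A change of 2-fold was found in 40.3% to 53.1% of these and a change of 4-fold in 83.6% to 88.9%.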
